A study of Homo sapiens with 12 samples.

How the data were processed

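RNA was measured in 12 libraries from 4 acute myeloid leukaemia cell lines, MOLM-14, OCI-AML3, MV4-11 and KG-1a, each treated for 12 h with DMSO, with 10 µM pioglitazone or with 10 µM darglitazone. Per the labels' protocols the libraries were made from total RNA with a stranded kit that removes ribosomal RNA, so transcripts without a poly(A) tail were counted too. Each line had 1 library per treatment. The cell line was therefore the replicate. The test of a treatment weighs the mean response over the lines against its spread between lines, and no repeat culture of a line enters any test.

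The values the authors deposited are estimated counts per transcript, without normalization. Of the values above 0, 89.8% were not whole at a tolerance of 1e-06. Per the submitters' processing notes, fastp, FastQC, STAR, featureCounts and DESeq2 were used with the GRCh38 build. featureCounts by default writes whole numbers, and the tool that gave the estimated counts is not given in the sources used here, nor is any version or the annotation release. The estimated counts can split reads between transcripts and between near-identical genes, which makes values of gene copies uncertain.

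The table held 203027 transcripts. The GENCODE release 29 annotation of GRCh38 matched 202941 of them (99.958%) when version numbers were ignored and 99.54% when they were not. The 86 unmatched transcripts held at most 0.0169% of a library's counts and were left out. Estimated counts were summed per gene over 57865 genes and rounded to whole numbers, and 57404 of these genes had a current symbol. Coordinates are those of GENCODE release 29.

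Genes with too few counts were removed by filterByExpr in edgeR 4.0.16 with the cell line as group (minimum count 10, minimum total 15), which left 15424. Library sizes were scaled by TMM. The main test was edgeR's robust quasi-likelihood F test of a model with cell line and treatment as terms, fitted to all 12 libraries with 6 residual degrees of freedom. It gave 4 contrasts: each drug against DMSO, darglitazone against pioglitazone, and the mean of both drugs against DMSO. A further model with a term for cell line by drug tested whether the mean response to the drugs differed between lines, with 3 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes carry the standard error (SE) of the fit and, where given, its 95% confidence interval. R 4.3.3, limma 3.58.1 and DESeq2 1.42.0 were also used.

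Before the data were examined, 36 gene lists were fixed from textbook knowledge of lipid metabolism, stress responses, cell cycle and blood cell types, and 35 of them had at least 5 tested members. The exception was the list of erythroid and megakaryocyte markers, with 4 tested genes of 18. Lists were tested with camera from limma at a preset correlation of 0.01 between genes and again with an estimated correlation, and adjusted over the lists of a contrast. For each list the number of members past the threshold was also counted with p-values adjusted over the list alone. In single lines, log2 ratios of TMM-scaled CPM with a prior count of 2 were compared with 10000 random lists matched on size and expression, as a description of those libraries.

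The rule for named genes was also fixed beforehand. It took the genes past the threshold with the same sign in all 4 lines or, where none passed, the 5 with the smallest p in each direction that were not clone names and had a mean log2 CPM of at least 1. It added up to 4 called members of each list (called when adjusted over the list alone), or else 2 members with the smallest p, and 20 preset genes of the PPAR pathway and its surroundings. For the contrast between the drugs the rule asked for the 8 largest changes per direction among genes past the threshold. As no gene passed, 5 were taken there too.

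Libraries of the same line deviated together: after removal of treatment means their correlations across genes ran from 0.6 to 0.85 over 12 pairs, against -0.53 to -0.04 over 54 pairs of different lines. Lines that differ in expression give such a pattern in any case, and removing means over lines pushes the correlations between lines below 0. These values therefore describe the libraries and do not test the pairing. The line pairs the libraries by design, so it stayed in the main model.

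Total estimated counts ran from 1.1 to 64.24 M (mega-counts) per library, a 58.6-fold range. A count of 3, taken as the lowest level distinguishable from 0, corresponded to 0.04 CPM in the deepest library and to 2.63 CPM in the shallowest. Such floors cover counting error only.

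Reads of other cell lines were estimated from genes specific to a line: autosomal protein-coding genes with at least 30 CPM in each library of the source line, at most 5% of that level in the other lines, and under 1% in the lowest library of the receiving line. This rule was set after an exploratory look had shown the pattern.

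The tests were run on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For pioglitazone the test recovered 49 and 74 of them and also called 22 unchanged genes of 14753 tested. For darglitazone it recovered 52 and 73 with 8 unchanged genes of 14669 called, and for the difference between the drugs 52 and 70 with 17 of 14945. For the mean of both drugs it recovered 55 and 81 with 9 of 14629. The test of a difference between lines recovered 6 and 37 and called 41 unchanged genes of 14679, so it makes more false calls than true calls of 2-fold changes. A list shifted 1.5-fold was called in 10 of 10 simulations with both correlations. The simulated genes were drawn independently of each other. In the data the estimated correlation with pioglitazone was 0.603 in the cholesterol list, 0.51 in the histone list and 0.692 in the G2/M list. These simulations therefore cannot show how either version of the list test performs on correlated genes.

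Alternatives covered the scaling, the low-count filter, the tool, the block, transcript-level tests, the prior count, the threshold and each library or line left out. Another 6 were added after the data had been seen: both pioglitazone libraries of doubtful quality left out, thinning to the smallest library, quality weights, a covariate for the rRNA-derived entry, GC offsets and subtraction of other lines' reads.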

Results

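The 12 libraries covered 4 human acute myeloid leukaemia cell lines under 3 treatments, DMSO as the control and pioglitazone or darglitazone at 10 µM for 12 h. Both drugs are thiazolidinediones, a class known as activators of the nuclear receptor PPARγ. The comparisons asked what each drug changed in the transcriptome, how far the drugs differed, and whether the lines responded differently. With 1 library per line and treatment, the line is the replicate (n = 4 per treatment), and nothing within a single line has a replicate check.

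Total estimated counts for DMSO, pioglitazone and darglitazone were 30.2, 23.13 and 9.42 M in MOLM-14 and 64.24, 1.1 and 20.27 M in OCI-AML3. They were 8.97, 7.53 and 32.2 M in MV4-11 and 8.72, 13.11 and 4.77 M in KG-1a. FP671120.3, an entry in the ribosomal DNA region of chromosome 21 (8210384 to 8211306, minus strand), took 23.535% of the counts in the KG-1a pioglitazone library and 6.174% in the OCI-AML3 pioglitazone library, against at most 0.145% in any DMSO library. Protein-coding genes held 55.578% and 74.795% of the counts in those 2 libraries. Both the shallowest library and the library richest in this rRNA-derived entry were thus pioglitazone libraries. Genes specific to another line were also present at low levels: KG-1a-specific genes stood at a median of 1.85% of their KG-1a level in the OCI-AML3 pioglitazone library, and MV4-11-specific genes at 4.1% of their MV4-11 level in the KG-1a darglitazone library.

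**Figure D1:**
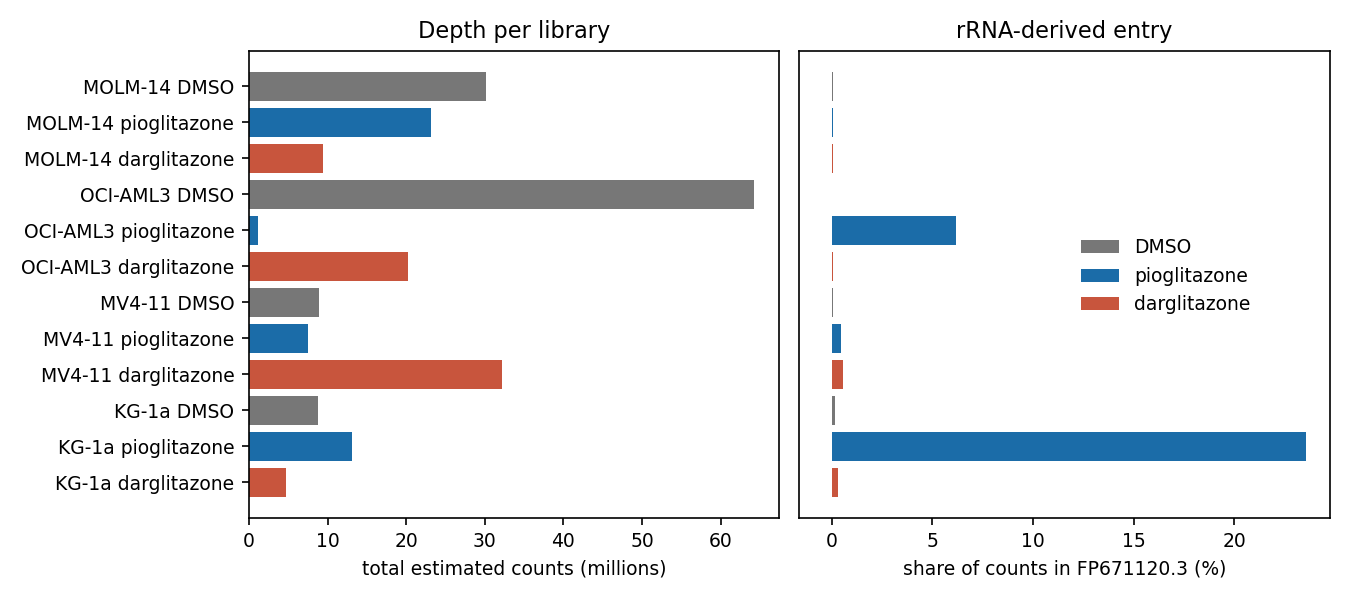
Bars give total estimated counts in M (left) and the percent of counts in the rRNA-derived entry FP671120.3 (right) for each of the 12 libraries, coloured by treatment. The OCI-AML3 pioglitazone library is the smallest at 1.1 M, and the KG-1a pioglitazone library has the highest share of the entry at 23.535%.

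With pioglitazone, genes of cholesterol and fatty acid synthesis stood higher than with DMSO. SCD, the desaturase that makes monounsaturated fatty acids (chromosome 10, 100347124 to 100364834, plus strand), had a log2 fold change of 1.0 (SE 0.15, 95% confidence interval 0.68 to 1.32, n = 4 lines), from 442 ± 278 CPM with DMSO to 803 ± 242 CPM (mean ± SD). HMGCS1, an enzyme early in the cholesterol pathway (chromosome 5, 43289395 to 43313512, minus strand), had 1.39 (SE 0.24), and its CPM went from 43.6 ± 23.5 to 135 ± 109. Both were higher in all 4 lines, SCD by 0.36 in MOLM-14, 1.21 in OCI-AML3, 1.37 in MV4-11 and 0.98 in KG-1a. Neither passed edgeR's test over all genes: SCD, the gene with the smallest value, had an adjusted p of 0.171, and HMGCS1 had 0.276.

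Of 24 tested cholesterol biosynthesis genes, 23 had a positive fold change, 18 were higher in all 4 lines, and 20 passed when adjusted over the list alone, while 0 passed over all genes. The list median was 0.69. FDFT1, which makes squalene, had a log2 fold change of 0.69 (SE 0.12), CYP51A1, a sterol demethylase, 0.71 (SE 0.14), and ACAT2 0.84 (SE 0.16). The feedback regulator INSIG1 had 1.02 (SE 0.2). The list differed from other genes by camera with an adjusted p of 5.81e-40 at the preset correlation, and had adjusted p = 0.14 with an estimated correlation. Its median in single lines was 0.21 in MOLM-14, 0.53 in OCI-AML3, 1.15 in MV4-11 and 0.71 in KG-1a, and the mean over its members averaged 0.64 ± 0.39 (SD, n = 4 lines). The OCI-AML3 and KG-1a values come from the libraries with 6.174% and 23.535% of the rRNA-derived entry.

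Fatty acid synthesis genes had a median of 0.57. Of 16 tested, 15 were positive and 5 passed when adjusted over the list alone, with 0 over all genes. The desaturase gene FADS2 had a log2 fold change of 0.79 (SE 0.13), FASN, the fatty acid synthase gene, 0.73 (SE 0.18), and ACACA, which makes malonyl-CoA, 0.61 (SE 0.16). For this list camera gave an adjusted p of 1.4e-13, and adjusted p = 0.12 with an estimated correlation. With the OCI-AML3 and KG-1a pioglitazone libraries left out, an alternative added after the data had been seen, its median was 0.32 and that of the cholesterol list 0.72. Pioglitazone is then measured in MOLM-14 and MV4-11 only. Their medians were 0.13 and 0.76 for fatty acid synthesis and 0.21 and 1.15 for cholesterol genes, so MV4-11 carries most of these values.

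**Figure D2:**
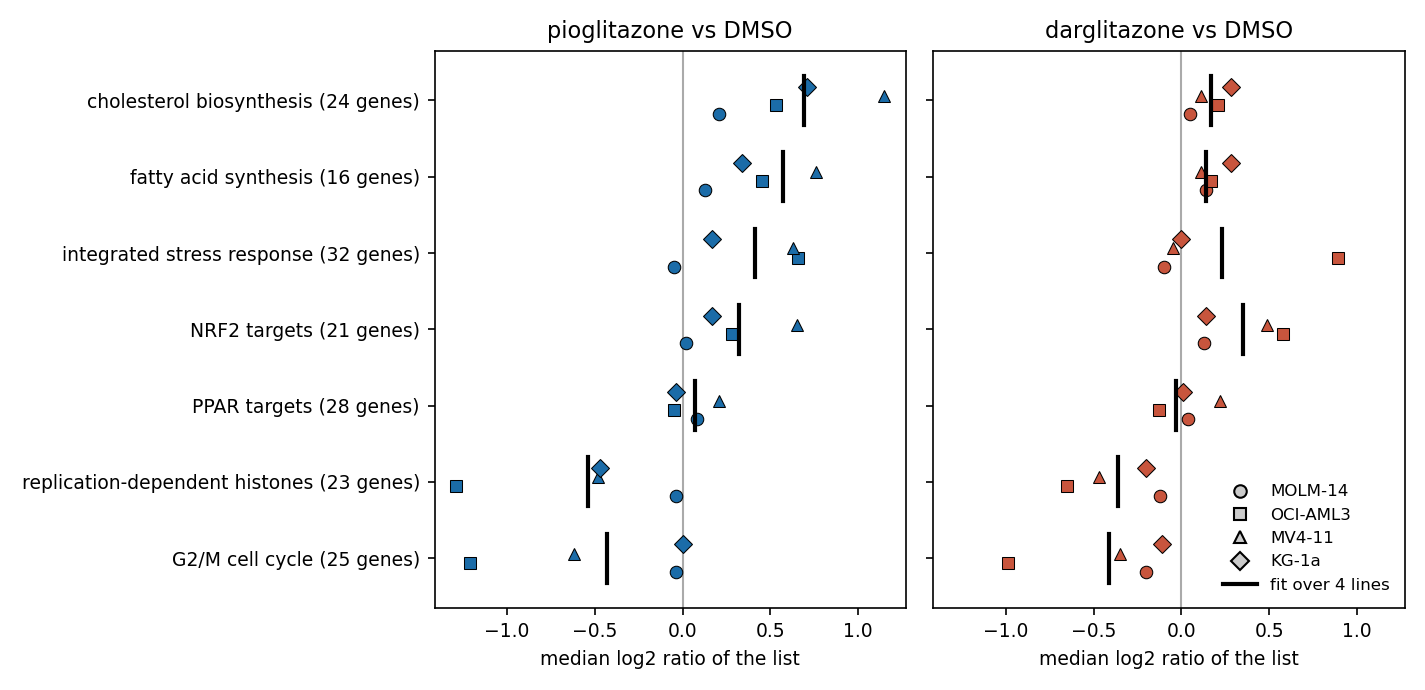
Median log2 ratio to DMSO of 7 gene lists in each of the 4 cell lines (symbols), with the median log2 fold change of the fit over 4 lines (black bars), for pioglitazone (left) and darglitazone (right). The cholesterol list lies above 0 in the 4 lines with both drugs, with fit medians of 0.69 and 0.17, and PPAR targets lie near 0, at 0.07 and -0.03.

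Genes of the oxidative stress regulator NRF2 mostly had positive fold changes with pioglitazone, less so in MOLM-14. HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, had a log2 fold change of 2.0 (SE 0.4) from a low level of 1.33 ± 0.779 CPM, and GCLM, for glutathione synthesis, 0.7 (SE 0.17). The NRF2 list had 19 of 21 positive members, 6 past the threshold when adjusted over the list alone and a median of 0.32, with a camera adjusted p of 1.61e-10 and adjusted p = 0.22 with an estimated correlation. Its median was 0.02 in MOLM-14, where 11 of 21 members were up and random lists ran from -0.08 to 0.05, and 0.28, 0.65 and 0.17 in OCI-AML3, MV4-11 and KG-1a. In the integrated stress response list 30 of 32 members were positive and 1, the asparagine synthetase gene ASNS (0.85, SE 0.21), passed when adjusted over the list alone. That list had a median of 0.41, an adjusted p of 5.2e-11, and adjusted p = 0.33 with an estimated correlation. Its median was -0.05 in MOLM-14, 0.66 in OCI-AML3, 0.63 in MV4-11 and 0.17 in KG-1a. Of 13 mitochondrially encoded genes, 11 were positive with a median of 0.36 and 4 passed when adjusted over the list alone, MT-CO1 (0.60, SE 0.13) among them. Their adjusted p was 5.17e-06, and adjusted p = 0.33 with an estimated correlation. The share of counts in mitochondrial rRNA was also higher in these libraries, from 7.25% with DMSO to 8.044% with pioglitazone in MOLM-14, 6.749% to 10.748% in OCI-AML3, 6.834% to 8.41% in MV4-11 and 10.021% to 10.319% in KG-1a. With darglitazone it was 7.755%, 6.785%, 9.87% and 13.297% in the same order of lines, where the medians of the mitochondrially encoded genes were 0.11, -0.12, 0.48 and 0.50. These shares are of all counts. The rRNA-derived entry took 23.535% of them in the KG-1a pioglitazone library and 6.174% in the OCI-AML3 one. That lowers the mitochondrial share there, so the KG-1a shares cannot be compared directly.

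Genes of cell division mostly had negative fold changes with pioglitazone, to a degree that varied between lines. All 23 tested replication-dependent histone genes had a negative fold change, 17 in each of the 4 lines, and 19 passed when adjusted over the list alone. H2BC14 had a log2 fold change of -0.90 (SE 0.22) and H2BC5 -0.63 (SE 0.16). The histone median was -0.54, with a camera adjusted p of 1.34e-17 and adjusted p = 0.27 with an estimated correlation. The 25 genes of the G2/M list were all negative, with a median of -0.43. Among them CDC20, an activator of the anaphase-promoting complex, had -0.68 (SE 0.16) and BIRC5, the survivin gene, -0.70 (SE 0.17), and 3 passed when adjusted over the list alone. The G2/M adjusted p was 5.35e-14, and adjusted p = 0.33 with an estimated correlation. Without the OCI-AML3 and KG-1a pioglitazone libraries the histone median was -0.30 and the G2/M median -0.37. Pioglitazone then rests on MOLM-14 and MV4-11, with histone medians of -0.04 and -0.48 and G2/M medians of -0.04 and -0.62. Both lists were lowest in the OCI-AML3 pioglitazone library of 1.1 M counts, at -1.29 and -1.21, and close to 0 in MOLM-14, at -0.04 and -0.04. In KG-1a the histone median was -0.47 but the G2/M median 0.00, with 14 of 25 members up.

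Granule genes of myeloid precursors had a median of -0.58 with pioglitazone, with 0 members past the threshold when adjusted over the list alone, an adjusted p of 0.00263, and adjusted p = 0.45 with an estimated correlation. Their KG-1a median was -1.26 with pioglitazone and 1.34 with darglitazone, the library in which MV4-11-specific genes stood at 4.1%; after subtraction of other lines' reads these medians were -0.27 and -0.31. MPO, for myeloperoxidase, had -0.59 (SE 0.26) with pioglitazone.

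Canonical PPAR targets were not called as a group. Of 28 tested, 16 were positive, with a median of 0.07 and an adjusted p of 0.4. In single lines, each a comparison of 2 libraries, the median was 0.08 in MOLM-14 and 0.21 in MV4-11, above the ranges of matched random lists (-0.07 to 0.06 and -0.16 to 0.13). It was -0.05 in OCI-AML3 and -0.04 in KG-1a, within those ranges. TXNIP, a regulator of thioredoxin and glucose uptake, was the member lowered when adjusted over the list alone (-0.98, SE 0.24), and ACSL3, an acyl-CoA synthetase gene (0.50, SE 0.12), the member raised. CPT1A, the carnitine transferase gene of fatty acid oxidation, had 0.33 (SE 0.13) and an adjusted p of 0.822, and PLIN2, for a lipid droplet protein, 0.19 (SE 0.34). PPARG itself had at most 91 counts in a library and did not pass the filter, and FABP4 and PDK4 had 0 counts in every library.

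Over all genes, edgeR called 0 of 15424 with pioglitazone. At an unadjusted p under 0.05 there were 919, 322 higher and 597 lower, where 771 are expected by chance. DESeq2 called 74 genes, 33 raised and 41 lowered, with SCD (adjusted p 2.55e-06), HMGCS1 (6e-06) and FDFT1 (8.88e-06) among the smallest values, and limma-voom called 0 with 939 at an unadjusted p under 0.05. edgeR's count moved under several alternatives. Without the MOLM-14 pioglitazone library 12 genes were raised and 2 lowered, HMGCS1 (adjusted p 0.000365) and SCD (0.00141) among those raised. RIT2 (17.43) and the entries OR11H3P and ENSG00000279639 (15.56) were too, all 3 at 0 counts in every DMSO library, so these fold changes give no size. With that library kept, thinning gave 14 raised and 6 lowered, and no low-count filter 93 and 130.

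**Figure D3:**
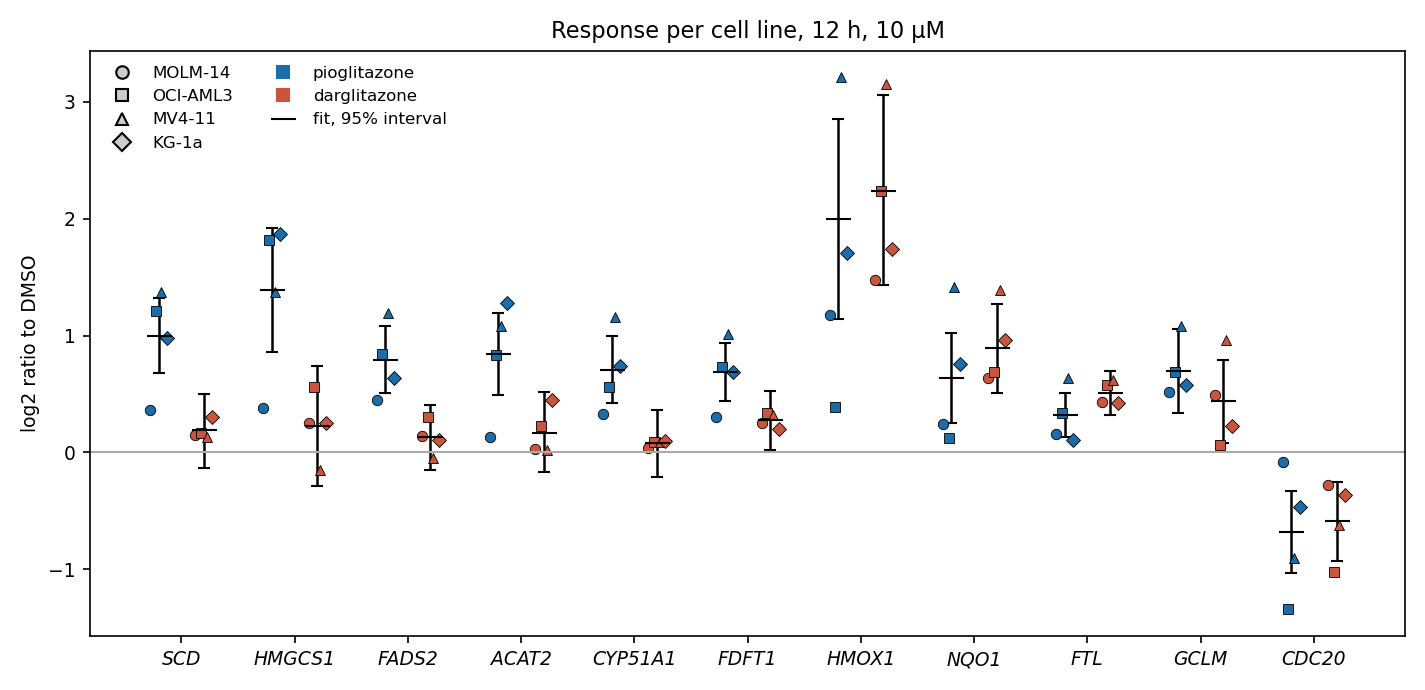
Log2 ratio to DMSO of named genes in each of the 4 cell lines (symbols), for pioglitazone (blue) and darglitazone (red), with the fitted log2 fold change and its 95% confidence interval (black). SCD lies between 0.36 and 1.37 with pioglitazone and between 0.13 and 0.30 with darglitazone, and HMOX1 between 1.48 and 3.15 with darglitazone; its OCI-AML3 pioglitazone point rests on 0.877 CPM, which is 1 count, and has no readable direction.

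With darglitazone the largest named change was in NRF2 targets. HMOX1 (chromosome 22, 35380361 to 35394214, plus strand) had a log2 fold change of 2.24 (SE 0.38, interval 1.43 to 3.06), between 1.48 and 3.15 in the single lines. FTL, the ferritin light chain gene, had 0.51 (SE 0.09) and NQO1, a quinone reductase gene, 0.89 (SE 0.18), both higher in the 4 lines. In KG-1a FTL went from 1570 to 2100 CPM and NQO1 from 5.54 to 10.9 CPM, in the library with MV4-11-specific genes at 4.1%. Both genes stood higher in MV4-11 with darglitazone, at 6210 and 108 CPM, so MV4-11 reads may add to these KG-1a values. The smallest adjusted p over all genes was 0.33, for HMOX1. Of 21 NRF2 targets, 20 were positive, 11 were higher in all 4 lines and 5 passed when adjusted over the list alone, with a median of 0.35. Camera gave an adjusted p of 7.84e-15, and adjusted p = 0.31 with an estimated correlation. The mean over its members averaged 0.47 ± 0.24 (SD, n = 4 lines).

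LDHA, for lactate dehydrogenase A, was lower with darglitazone in each line (-0.41, SE 0.09) and was the member of the hypoxia and glycolysis list that passed when adjusted over the list alone. All 25 G2/M genes were again negative, 15 in each of the 4 lines, with a median of -0.41 and CDC20 at -0.59 (SE 0.16). None of them passed when adjusted over the list alone, and 13 had an unadjusted p under 0.05. By camera the list had an adjusted p of 1.39e-17, and adjusted p = 0.45 with an estimated correlation. The G2/M median was -0.99 in OCI-AML3, -0.35 in MV4-11 and -0.20 in MOLM-14, but -0.11 in KG-1a. There 10 of 25 members were up, and the median lay within the random range of -0.15 to 0.08. The 23 histone genes were all negative too (median -0.36, adjusted p 9.42e-13, adjusted p = 0.45 with an estimated correlation), with 0 past the threshold when adjusted over the list alone. The cholesterol list had a median of 0.17, with 20 of 24 positive and 0 past the threshold when adjusted over the list alone. Its adjusted p was 0.000469, and adjusted p = 0.57 with an estimated correlation. PPAR targets had a median of -0.03 and an adjusted p of 0.195; in MV4-11 it was 0.22, above the range of -0.10 to 0.14 for random lists, and in MOLM-14, OCI-AML3 and KG-1a 0.04, -0.13 and 0.01, within their ranges. Inflammatory genes of the NF-kB list had a median of 1.53 in OCI-AML3 but -0.12 in MOLM-14, -0.12 in MV4-11 and 0 in KG-1a, and IL1B, the interleukin 1 beta gene, went from 4.74 to 45.6 CPM in OCI-AML3.

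edgeR called 0 genes with darglitazone and had 525 at an unadjusted p under 0.05, below the 771 expected by chance. DESeq2 called 6, 4 raised and 2 lowered, HMOX1 (0.000453), LDHA (0.000686), FTL (0.00139) and NQO1 (0.0233) among them. limma-voom called 0, with 1428 at an unadjusted p under 0.05. Without the OCI-AML3 darglitazone library edgeR raised 3 genes, KRT82 (18.56), OR11H1 (16.31) and RIT2 (19.57), again at 0 counts in every DMSO library, so these give no size.

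Sterol genes, and to a lesser extent fatty acid genes, mostly had lower values with darglitazone than with pioglitazone. SCD differed by -0.81 (SE 0.15, interval -1.13 to -0.49), HMGCS1 by -1.17 (SE 0.24, interval -1.70 to -0.64) and CYP51A1 by -0.63 (interval -0.92 to -0.34). TFRC, the transferrin receptor gene, differed by -0.53 (interval -0.78 to -0.28). Of 24 cholesterol genes, 23 were lower with darglitazone, 15 of them in all 4 lines, and 18 passed when adjusted over the list alone. The list median was -0.50, with a camera adjusted p of 1.16e-25 and adjusted p = 0.35 with an estimated correlation. Of 16 fatty acid synthesis genes 13 were lower and 3 higher, 3 were lower in all 4 lines, and 3 passed when adjusted over the list alone. Their median was -0.37, with an adjusted p of 1.03e-06 and adjusted p = 0.35 with an estimated correlation, and the medians against DMSO in MOLM-14 were 0.13 with pioglitazone and 0.14 with darglitazone.

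At an unadjusted p under 0.05, 323 genes were higher with darglitazone than with pioglitazone and 218 lower. An ATXN7 entry (chromosome 3, 63864557 to 64003462, plus strand) differed by 3.84 (SE 0.93, adjusted p 0.98). It was at 0 CPM with pioglitazone in MOLM-14, OCI-AML3 and MV4-11, against 5.99, 7.46 and 3.17 with darglitazone, so its size depends on the prior count. It overlaps another ATXN7 entry that differed by -0.20, so its counts are uncertain, and it passed without the KG-1a pioglitazone library (adjusted p 0.0357). GCM1, a transcription factor gene, differed by 2.65 (SE 0.67, adjusted p 0.98), at 3.75 and 13.6 CPM in MV4-11 and 1.61 and 18.2 in KG-1a.

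No difference was shown for HMOX1 (0.25, SE 0.37) or for the NRF2 list (median 0.10, adjusted p 0.827), nor for G2/M genes (median 0.00, adjusted p 0.918). CPT1A differed by 0.05 with an interval of -0.24 to 0.34, and PLIN2 by -0.04 with an interval of -0.79 to 0.70. edgeR called 0 genes between the drugs, where the smallest adjusted p was 0.98 for SCD, and 541 had an unadjusted p under 0.05. DESeq2 called 12, with SCD and HMGCS1 at 0.00149 and FADS2 at 0.00491, and limma-voom 0, with 867 at an unadjusted p under 0.05. Without MOLM-14 edgeR called 4.

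The fold changes of both drugs share the same DMSO libraries. Across 15424 genes, which are not independent replicates, they correlated with Pearson's r of 0.387 and Spearman's rho of 0.35. In 20 simulations, unchanged drugs against the same controls gave a mean r of 0.421 (0.398 to 0.444), so the observed r lay below that range. The covariance was 0.0802 against a mean of 0.0721 in the simulations (0.0659 to 0.0772), above that range by either value, with a difference of 0.0081 from the mean. The r and the covariance thus left the simulated ranges in opposite directions. As the simulated genes were drawn independently of each other, these ranges cannot show the spread for correlated genes, and neither departure decides anything. With each drug's effect taken from different lines, r averaged 0.034 over 6 choices.

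For the mean of both drugs against DMSO, edgeR called 0 genes and 750 had an unadjusted p under 0.05. DESeq2 called 36 and limma-voom 0, with 1202 at an unadjusted p under 0.05. By camera 9 lists were higher and 9 lower at the preset correlation and 0 with an estimated one. NRF2 targets had a median of 0.33 (adjusted p 6.99e-16, adjusted p = 0.15 with an estimated correlation) and 8 members past the threshold when adjusted over the list alone. Histone genes had a median of -0.45 (adjusted p 1.3e-20, adjusted p = 0.21 with an estimated correlation) and 19 such members.

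In the test of a response that differs between lines edgeR called 1 gene, AL139099.4, at an adjusted p of 0.0237 (chromosome 14, 49586579 to 49586878, plus strand). This entry covers the same span as RN7SL1, a 7SL RNA gene at 49586580 to 49586878, so its counts are uncertain. Its CPM for DMSO, pioglitazone and darglitazone was 10.9, 50 and 103 in OCI-AML3 and 643, 92.3 and 210 in KG-1a. ITGA6, an integrin gene, came next with an adjusted p of 0.154. The count was 0 with a non-robust spread, 0 with transcripts and 0 without the KG-1a pioglitazone library, and the test called 41 unchanged genes in simulated data. At an unadjusted p under 0.05 there were 470 genes. DESeq2's likelihood ratio test called 64 and limma-voom 2.

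**Figure D4:**
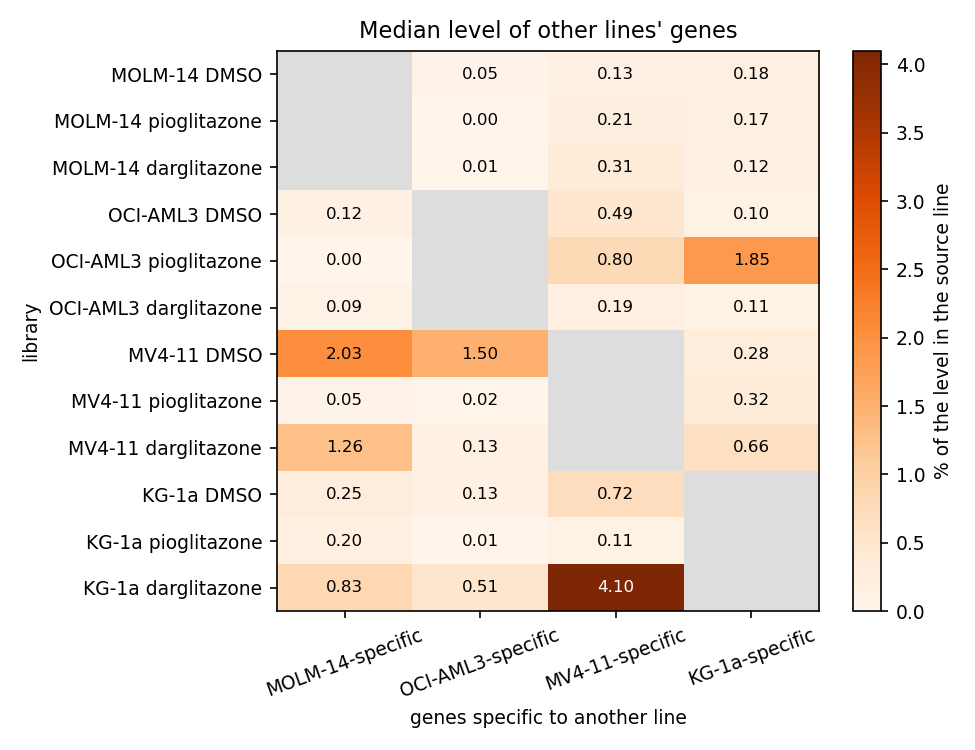
Each cell gives the median level of genes specific to a source line (columns) in a library of another line (lines of the grid), in percent of their level in the source line; grey cells are a line's own libraries. Of the 36 pairs of library and source 5 lie above 1%, the highest being MV4-11-specific genes in the KG-1a darglitazone library at 4.1%.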

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

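The tests chosen after the result was seen are those of poor libraries for the cholesterol list, of GC offsets for the cholesterol and histone lists, of the subtraction of other lines' reads, of reads of other lines in single libraries, of fewer cycling cells for the histone list, and the splits of the samples for gene counts with either single drug, between the drugs and for both drugs.

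The cholesterol list was higher with pioglitazone, with a median of 0.69. Poor libraries as the only source are argued against. The median in MOLM-14, whose pioglitazone library held 0.061% of the rRNA-derived entry, was 0.21, above the random range of -0.07 to 0.05. In MV4-11, at 0.472%, the median was 1.15, but that share also exceeded the highest DMSO share of 0.145%. OCI-AML3 and KG-1a, at 6.174% and 23.535%, had 0.53 and 0.71. A part of library quality in the size of the rise is not excluded, since MOLM-14 had the smallest median. The median of the fit was 0.71 with GC offsets and 0.71 after subtraction of other lines' reads, so neither accounts for the rise. Chance is not excluded, as 4 of 35 splits of the 8 libraries, the real one included, gave a median as large in size, the highest other being 0.74; among the 8 splits that part every line, too few for a share under 0.05, the next after the real one was 0.55. A response of sterol genes to pioglitazone stays a hypothesis, found and tested on the same libraries.

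Genes of another line appeared in single libraries. ITGA6 and CYP1B1, high in KG-1a, were at 7.9 and 3.51 CPM in the OCI-AML3 pioglitazone library against 0.389 and 0.732 with DMSO (CPXM1, at 1 count, cannot be read there), and KG-1a-specific genes there had a median of 1.85% of their KG-1a level, so KG-1a reads may account for these values. In the OCI-AML3 darglitazone library that median was 0.11%, which argues against KG-1a reads for ITGA6, CPXM1 and CYP1B1 at 5.94, 2.19 and 3.56 CPM there, and their origin stays open. The granule list in KG-1a went from a median of 1.34 with darglitazone to -0.31 after subtraction, with shares taken from genes outside the list. Granule genes summed to 4217.9 CPM in MV4-11 with DMSO, against 380.2 in the KG-1a darglitazone library. Removing 4.1% of an MV4-11 profile thus lowers this list whatever its origin, and the fall itself decides nothing. The share of 4.1% leaves MV4-11 reads a candidate source of the higher value. Reads were also subtracted from the KG-1a DMSO library, where MV4-11-specific genes stood at 0.72%, against 0.11% with pioglitazone. The granule example was added after both its ratio and the share had been seen, and no biological explanation was tested.

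Histone genes had negative medians with both drugs, -0.54 and -0.36, but with darglitazone 0 of 23 passed when adjusted over the list alone, and an estimated correlation gave adjusted p = 0.27 and adjusted p = 0.45. A lower yield of all short RNAs without a poly(A) tail is argued against. The median of 219 other short entries was 0.05 with pioglitazone (quartiles -0.35 to 0.51) and 0.16 with darglitazone (-0.08 to 0.41). RN7SL1, RN7SL2 and RN7SK, 7SL and 7SK RNA genes, took 6.028, 5.658 and 6.411% of counts with DMSO, pioglitazone and darglitazone in MOLM-14. The shares were 5.255, 3.896 and 5.977% in OCI-AML3, 5.489, 5.656 and 5.377% in MV4-11, and 8.453, 5.466 and 8.797% in KG-1a. The rRNA-derived entry lowers such shares in the OCI-AML3 and KG-1a pioglitazone libraries, so the yield of these RNAs there is left open. With GC offsets the histone median closer to 0 was still -0.39. Fewer cells in S phase and mitosis cannot be told apart from another origin, because the highest of the G1/S and G2/M medians was -0.09, 0.01 short of the bound of -0.1 set for it. An allowance for the spread of the members was added after that value was seen, and without it the rule would have gone against the explanation. The bound too was written after the result was seen, and a miss by 0.01 cannot rule the explanation out. The second condition, the same sign of the histone and G2/M medians, held in 7 of 8 drug libraries, as many as the rule asked for. Single libraries also went the other way. In OCI-AML3 with darglitazone the G1/S median was 0.16, with 20 of 25 members up, beside -0.65 for histones. In KG-1a with pioglitazone the G2/M median was 0.00 beside -0.47.

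Regrouping the libraries also bears on the counts of lists. The numbers of splits here include the real one. With pioglitazone 16 lists passed, and 4 of 35 splits gave as many, up to 19 in the others. With darglitazone 15 passed and 4 of 35 splits gave as many, up to 17, and for the NRF2 median of 0.35 again 4 of 35 in size, up to 0.44. Over all 35 splits chance is not excluded for these; among the 8 that part every line, too few for a share under 0.05, the highest others were 16 and 13 lists and a median of 0.29. Between the drugs 4 lists passed, 31 of 35 splits gave as many and one gave 15, and the cholesterol median of -0.50 was matched in size by 5 of 35, up to 0.6; of the 8 that part every line the highest others were 10 lists and 0.39. For both drugs together 18 lists passed against at most 16 in the other splits, 1 of 100. That share is under 0.05, but the line pairs the libraries, and the 16 splits that part every line, with 13 as the highest other, are too few for such a share. Whether chance gave this count is left open, and 0 lists passed with an estimated correlation. A gene count of 0 is matched by every split whatever the grouping, so these say nothing on chance: 35 of 35 with pioglitazone (highest other 2), 35 of 35 with darglitazone (2), 35 of 35 between the drugs (1) and 100 of 100 for both drugs. A split there called 43 genes, which points to some structure of the samples, but its source was not tested and the splits that part every line called at most 1. For the difference between lines, 72 of 81 choices of the control library gave at least 1 gene, up to 19.

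AL139099.4 was called for a response that differs between lines, with an adjusted p of 0.0237 in edgeR. The call was lost with a non-robust spread, with transcripts and without the KG-1a pioglitazone library, at 0 genes each. Its span is that of RN7SL1, and the test called 41 unchanged genes in simulated data.

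A line stood apart from the other 3 in 8 of 178 groups of a gene and a drug, where 8.9 are expected by chance. With pioglitazone these were DECR2 in KG-1a at -0.88 against -0.30 to -0.21, and MPC2 in OCI-AML3 at -0.83 against 0.17 to 0.23. With darglitazone they were LDHA at -0.59, HSP90B1 at -0.95 and SQSTM1 at 1.49 in OCI-AML3, ACOX3 at 1.0 in KG-1a, and PDHA1 at -0.04 and PAX5 at 0.04 in MOLM-14.

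Outside the comparisons, the rRNA-derived entry held a larger share of counts than in any DMSO library in 5 drug libraries. The shares were 6.174% in OCI-AML3 and 23.535% in KG-1a with pioglitazone, 0.472% and 0.542% in MV4-11 with pioglitazone and darglitazone, and 0.319% in KG-1a with darglitazone. Genes specific to another line stood above 1% of their source level in 5 pairs. MOLM-14-specific genes were at 2.03% in the MV4-11 DMSO library and 1.26% in the MV4-11 darglitazone library, over 4 genes. OCI-AML3-specific genes were at 1.5% in the MV4-11 DMSO library over 11 genes, MV4-11-specific genes at 4.1% in the KG-1a darglitazone library over 6 genes, and KG-1a-specific genes at 1.85% in the OCI-AML3 pioglitazone library over 73 genes.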

How the results depend on the processing

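Of 36 alternatives, 6 were chosen after seeing the data: the poor libraries left out, thinning, quality weights, the rRNA covariate, GC offsets and subtraction of other lines' reads. For named genes 6917 of 7056 values under alternatives kept direction and side of the threshold, 114 passed it and 25 changed sign. As 0 genes passed in the main contrasts, keeping the side means staying uncalled, so much of this agreement was set by the starting point. A change of sign was counted only where the original value exceeded its SE, or a list median was at least 0.05 in size, a rule set after the values were seen, and 44 of 230 pairs of gene and contrast lay under 1 SE. An adjusted p under 0.10 moved no count of genes. For lists it would have added immediate early genes (0.0528), mitochondrial fatty acid oxidation (0.0636) and the mitoNEET family (0.0906) with darglitazone, and histones (0.0661) between the drugs.

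Without the low-count filter edgeR raised 93 and lowered 130 genes with pioglitazone, raised 42 and lowered 34 with darglitazone, and called 88 between the drugs, 148 for both drugs and 124 between lines. DESeq2 gave 33, 41, 4, 2, 12, 36 and 64 in that order. limma-voom called 2 genes between lines and 8 lists between the drugs. With no replicate block 2 lists differed between the drugs, against 4 with it; the lists with pioglitazone, darglitazone and both drugs numbered 15, 12 and 14, and the block moved no other count by over 1.5 times. The count of 1 gene between lines became 0 with a non-robust spread, 0 with transcripts and 0 without the KG-1a pioglitazone library. With an estimated correlation camera called 0 lists with pioglitazone, 0 with darglitazone, 0 between the drugs and 0 for both drugs. The medians of 0.69 and -0.50 for cholesterol genes, 0.57 for fatty acid synthesis, 0.35 for NRF2 targets, -0.54 for histones and -0.41 for G2/M were then not called; the test's allowance for correlated genes is the only thing that differs.

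With both poor pioglitazone libraries left out, 85 genes were called between lines. That fit has fewer residual degrees of freedom than the 3 of the main one. OCI-AML3 and KG-1a then rest on a single darglitazone library each, so the count cannot be read as a number of true differences. The medians with pioglitazone were then 0.72 for cholesterol genes, 0.32 for fatty acid synthesis and -0.30 for histones, from MOLM-14 and MV4-11 only. Thinned to the smallest library, edgeR raised 14 and lowered 6 genes with pioglitazone and called 1 between the drugs, 5 for both and 4 between lines. With quality weights voom raised 2 with darglitazone and called 2 for both, 13 between lines and 9 lists between the drugs. With the rRNA covariate 2 genes differed between the drugs and 8 between lines, and 10 lists passed with pioglitazone and 11 for both drugs. After subtraction of other lines' reads 2 genes differed between lines. The cause was not tested for these.

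With each line or library left out in turn, genes raised with pioglitazone ranged from 0 to 12, the highest without the MOLM-14 pioglitazone library (3 without MOLM-14), and those lowered from 0 to 2. Genes raised with darglitazone ranged from 0 to 3, the highest without the OCI-AML3 darglitazone library, those between the drugs from 0 to 4, the highest without MOLM-14, and those for both drugs from 0 to 3. Genes between lines ranged from 0 to 22 and lists between the drugs from 3 to 9, both highest without the OCI-AML3 darglitazone library. Each library or line left out also took the test between lines below its 3 residual degrees of freedom.

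List medians that changed sign were small. NRF2 targets between the drugs went to -0.05 without the poor libraries and -0.04 with GC offsets, and histones to -0.10 without the poor libraries and -0.10 with the rRNA covariate. The integrated stress response went to -0.04 with darglitazone without OCI-AML3 and -0.03 without its darglitazone library (up to 0.34 over the libraries and lines left out), and between the drugs to 0.07 without MV4-11 and 0.03 without its pioglitazone library (down to -0.37).

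With the rRNA covariate single genes changed sign: with pioglitazone CEBPE went to 0.63, MPC1 to 0.01, CD33 to 0.01, FKBP4 to 0.01, HSF1 to 0.05, RPS15 to 0.00, IFI44L to 0.19, GLA to 0.00 and CD4 to 0.17, and CITED2 to 0.06 for both drugs. Without the poor libraries CEBPE went to 0.09, HSF1 to 0.00 and CD4 to 0.08. Thinning gave MPC1 0.11 with pioglitazone and 0.10 for both drugs, MYLIP -0.08 and PAX5 -0.23 with darglitazone, and PPARA -0.26 between the drugs. With no replicate block CD4 went to 0.04, ITGAM to -0.28, IFI6 to -0.05 and STAT5A to -0.03. Quality weights gave CD4 0.04 and ITGAM -0.03, and ITGAM ranged from 0.00 without OCI-AML3 to 0.76 without KG-1a.

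No value was possible for both drugs with only 2 treatments in the fit, nor for the difference between lines without the block, with 2 treatments or with a DMSO library left out. Depth limits the OCI-AML3 pioglitazone library most, where 1 count was worth 0.877 CPM.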

Other observations

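The lists below were fixed before the data were examined; no test here was chosen afterwards apart from the comparison of single OCI-AML3 libraries. Nuclear genes of respiratory complexes III to V mostly had negative fold changes with both drugs, but 0 of 35 passed when adjusted over the list alone with either. Their median was -0.20 with pioglitazone (35 tested, 6 positive, adjusted p 9.21e-06 by camera, adjusted p = 0.33 with an estimated correlation). With darglitazone it was -0.14 (2 positive, adjusted p 1.91e-07 by camera, adjusted p = 0.45 with an estimated correlation). Mitochondrially encoded genes went the other way, at 0.36 and 0.20. With pioglitazone the complex III to V medians in OCI-AML3 (-0.30) and KG-1a (-0.10) lay within the ranges of matched random lists (-0.43 to -0.08 and -0.21 to 0.01). In MOLM-14 (-0.06) and MV4-11 (-0.11) they lay at the lower end of theirs. With darglitazone MOLM-14 (-0.02) and KG-1a (-0.12) were within their ranges, and OCI-AML3 (-0.38) and MV4-11 (-0.11) below them. G1/S genes had medians of -0.18 and -0.09, and heat shock genes -0.09 (adjusted p 0.181) and -0.13 (adjusted p 0.00367, adjusted p = 0.42 with an estimated correlation). In OCI-AML3 the G1/S median was -0.26 with pioglitazone, within the random range of -0.44 to -0.02, and 0.16 with darglitazone. HSPA5, an endoplasmic reticulum chaperone gene, had a log2 fold change of -0.41 (SE 0.14) with darglitazone and was lower in the 4 lines.

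Stress and inflammatory genes were higher in the OCI-AML3 darglitazone library than in its DMSO library, a comparison of single libraries with no replicate check. The integrated stress response list had a median of 0.89 there, against -0.10 in MOLM-14, -0.05 in MV4-11 and 0 in KG-1a with darglitazone. With pioglitazone this list also stood higher in OCI-AML3, at 0.66, and in MV4-11, at 0.63. Its rise in OCI-AML3 was thus not particular to darglitazone, and both OCI-AML3 values share the same DMSO library. In the OCI-AML3 darglitazone library GDF15, a stress-induced cytokine gene, was at 27.7 CPM against 1.94 with DMSO. SQSTM1, for an autophagy receptor, had a log2 ratio of 1.49 there. Without that library the list's median with darglitazone was -0.03, and the difference between the lines was not tested for the list.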
